A study of Mus musculus with 6 samples.

How the data were processed

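RNA was profiled from endothelial cells of embryonic mouse hearts. Per the labels, the mice carried Pdgfb-iCreERT2-IRES-EGFP, a transgene that expresses a tamoxifen-inducible Cre recombinase and green fluorescent protein in endothelial cells. Tamoxifen was given at embryonic day 13.5, hearts were taken at embryonic day 14.5, and cells positive for both CD31 and green fluorescence were sorted by flow cytometry. The crosses left 2, 1 or 0 intact copies of Dll4, which encodes a Notch ligand, in the recombined cells. These groups are called wt, het and KO below. RNA was amplified with the SMART-Seq v4 kit, which primes from poly(A) tails and does not mark strand, and libraries were made with Nextera XT, per the labels' protocols. The labels name an Illumina HiSeq instrument and disagree on whether reads were single or paired.

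The authors deposited one table of expected counts, estimated reads per gene that need not be whole, with 1 column for each of the 6 libraries. CASAVA, cutadapt and RSEM on genome build GRCm38 are named, without versions, per the submitters' processing notes. RSEM divides reads that match several genes by their estimated abundance, so genes with near-identical copies, processed pseudogenes and overlapping transcripts carry uncertain values, and sense and antisense partners cannot be told apart without strand. The table's name refers to Ensembl release 76. Symbols and positions were taken here from GENCODE mouse release M21 on GRCm38, which matched 97.7% of the 41214 gene identifiers. No column of another sample was present.

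Expected counts were rounded to whole numbers. Of the values in a library, between 4.29% and 5.87% were not whole. Totals ranged from 1537908 to 6501798 counts. In R 4.3.3, edgeR 4.0.16 was used with TMM scaling factors, the filterByExpr filter on the 3 groups with its minimum count of 10, a robust quasi-likelihood fit and two-sided quasi-likelihood F tests. The 6 libraries entered one fit, which left 3 residual degrees of freedom. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the 10952 genes tested. KO was compared with wt, het with wt, and KO with het. A further contrast set het against the mean of wt and KO on the log scale, and a separate fit used the number of lost alleles as a numeric term. CPM were computed with the TMM-scaled library sizes and are given as mean ± SD with n = 2 libraries per group. Every adjusted p of a gene comes from this edgeR test with Benjamini-Hochberg adjustment unless another tool is named.

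Of 32 gene lists fixed before the data were examined, 31 had at least 3 tested members. They covered Notch signalling, arterial, venous and other endothelial identity, growth, the cell cycle, metabolism, and markers of other cell types, RNA quality and sex. Each was tested two-sided with camera (limma 3.58.1) at a preset correlation between genes of 0.01, with Benjamini-Hochberg adjustment over the lists. The test was repeated with the correlation estimated from the data and with fry. No list passed with an estimated correlation in any of the 3 comparisons. That version takes its p from the 3 residual degrees of freedom of the fit, so it has little power here. Arterial genes in het against wt and Notch targets in KO against wt did not pass although their estimated correlations, -0.00498 and -0.0734, were below 0.01. Other called lists had estimates far above 0.01. Ribosomal proteins had 0.648 in KO against wt, 0.638 in het against wt and 0.631 in KO against het. In het against wt the estimate was 0.981 for mitochondrial transcripts, 0.902 for macrophages and 0.553 for mural cells and fibroblasts. The preset p of such lists may be too small, because their members vary together. Where the estimate was below 0.01, not passing this version does not by itself show that a call at the preset value came from correlated genes.

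The naming rule was also fixed beforehand. It took Dll4, then in each comparison the 5 largest rises and 5 largest falls among called genes with an average log2 CPM of at least 3 and no overlap between the groups. Predicted genes were left out, that is, symbols starting with Gm and a digit, ending in Rik, ending in -ps with or without a number, or missing. From each list described, up to 4 members were taken in order of adjusted p in KO against wt. A gene that this rule named is not reported here. Where all libraries of a group held 0 counts, the fold is given as a bound against a floor of 3 counts over the group, which covers counting error only.

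The procedure was tested on simulated counts for the same genes, means and library sizes. Of 100 genes changed by 1 on the log2 scale, 62 were recovered in KO against wt, 54 in het against wt, 63 in KO against het and 65 off the midpoint. Of 100 genes changed by 0.5 per allele, 56 were recovered by the trend. Unchanged genes called in error numbered 18, 18, 10, 18 and 7 in the same order. In KO against wt, off the midpoint and in the trend, this was more than the nominal rate allows beside these recoveries. The genes changed by 0.5 per allele also differed in het against wt and KO against het. Their calls were not counted there, so the share of errors in these comparisons is not known.

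Alternatives fixed beforehand were RLE size factors, scaling by library size only, no filter beyond 1 count, a mean CPM of at least 5, DESeq2 1.42.0, limma-voom, a fit of the 2 compared groups alone (for genes), and each library left out in turn. Added after the data were examined were thinning to equal totals, thinning to equal effective depth (library size times TMM factor), list tests in a fit of the 2 compared groups alone, removal of a trend with C-rich transcript windows, removal of 7 abundant genes (Lars2, both mitochondrial ribosomal RNA genes, Gm42418, Rn7s1, Rn7s2 and Rn7sk), and protein-coding genes only. The labels give several litters from independent females but tie none to a library. The p-values therefore measure only the spread between these libraries, which may be technical. They give no batch, litter or sex per library.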

Results

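The series asks how normal, reduced and absent Dll4 in coronary endothelial cells affects their expression during arterial development. Endothelial cells sorted from embryonic hearts 1 day after tamoxifen gave 6 libraries, 2 for each of the groups wt, het and KO. The wt libraries held 2521534 and 1732136 counts, the het libraries 1537908 and 3165552, and the KO libraries 6501798 and 4988014. Between 13741 and 14839 genes had a count above 0 in a library. No pair of libraries was a duplicate, since replicates differed by 3.06 to 5.53 times the sampling variance per gene. The first principal component of log2 CPM carried 58.1% of the variance and set both KO libraries, at 51.2 and 56.7, apart from the other 4, which lay between -31.1 and -24.0. The second component, with 16.8%, set het replicate 2, at -40.2, apart from het replicate 3, at 1.46. Het replicate 3 correlated with wt replicates 4 and 5 (Pearson's r across genes 0.960 and 0.957) more than with het replicate 2 (0.949), across genes that are not independent.

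The KO libraries also differed from the rest in their makeup. Lars2, the gene of the mitochondrial leucyl-tRNA synthetase, which contains sequence resembling ribosomal RNA, took 16.5% ± 0.280 of counts in wt and 16.7% ± 0.491 in het but 0.0592% ± 0.00278 in KO (SD, n = 2 each). Mitochondrial ribosomal RNA took 1.80% ± 0.662, 2.53% ± 0.974 and 0.102% ± 0.00919. Messenger RNA encoded in mitochondria took 1.48% ± 0.428, 2.15% ± 0.954 and 0.951% ± 0.107. The 7SL RNA genes Rn7s1 and Rn7s2 together took between 0.129% and 0.234% in the wt and het libraries. In the KO libraries they took 0.00125% and 0.00235%. The labels give no preparation or sequencing date, so a batch of the KO libraries and the genotype cannot be told apart.

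**Figure D1:**
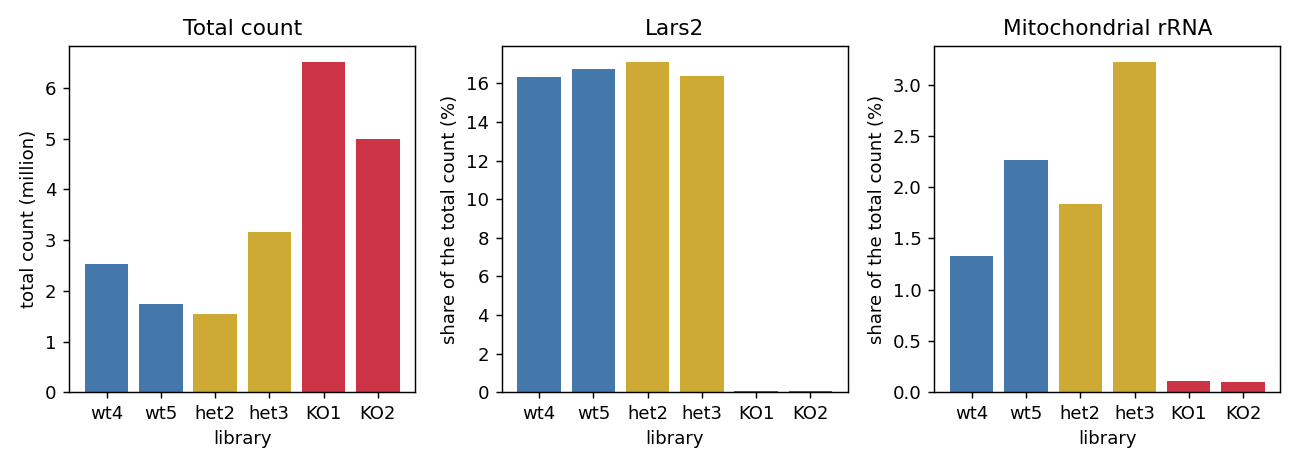
Total count, and the percentage of it assigned to Lars2 and to mitochondrial ribosomal RNA, in each library; bars are single libraries of wt (blue), het (yellow) and KO (red). Lars2 stood between 16.3% and 17.1% in the wt and het libraries and at 0.0572% and 0.0611% in the KO libraries.

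Dll4, on chromosome 2 from 119325784 to 119335962 (GRCm38; ENSMUSG00000027314), followed the labelled genotypes. Its level was 189 ± 9.32 CPM in wt, 83.5 ± 3.30 in het and 16.5 ± 3.97 in KO (SD, n = 2). The log2 fold change was -3.50 ± 0.16 (SE) for KO against wt, -1.18 ± 0.15 for het against wt and -2.32 ± 0.17 for KO against het, with edgeR adjusted p = 2.01e-12, 7.35e-04 and 1.76e-09. The het call was lost without wt replicate 4 (log2 fold change -1.13, adjusted p = 0.0859).

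The comparison of KO with wt asks what full loss of Dll4 changes. Arterial genes fell. Gja5, which encodes the arterial gap junction protein connexin 40, went from 189 ± 10.8 to 8.95 ± 2.93 CPM, 21.5-fold lower. Cxcr4, a chemokine receptor used in coronary artery assembly, was 25.5-fold lower, from 83.7 ± 13.6 to 3.37 ± 1.47 CPM. The netrin receptor gene Unc5b was 6.69-fold lower and Slc45a4 8.25-fold lower. Their edgeR adjusted p lay between 9.86e-13 and 4.39e-11. Of 25 tested genes on the arterial list, 16 fell and none rose. Adjusted over the list alone, 17 fell. The list's median log2 fold change was -1.39, camera gave adjusted p = 2.58e-20, and adjusted p = 0.0997 with an estimated correlation.

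Direct Notch target genes fell as well, 5 of 9 over all genes and 7 adjusted over the list alone, with none higher. Hey1, a transcriptional repressor induced by Notch, went from 117 ± 4.50 CPM in wt to 23.9 ± 3.32 in KO. Notch1 itself went from 368 ± 53.5 to 130.5 ± 32.4 CPM and Hes1 from 97.6 ± 1.16 to 49.8 ± 0.821 CPM. Heyl stood at 7.54 ± 0.974 and 1.44 ± 1.08 CPM and lost its call without wt replicate 4, wt replicate 5 or KO replicate 2. Camera gave adjusted p = 3.60e-04 for this list, and adjusted p = 0.278 with an estimated correlation. Among genes of BMP signalling and the response to flow, 7 of 13 fell, with the same count over the list alone, including the receptor gene Bmpr2 (4.57-fold lower), the flow-responsive factor Klf4 (8.02-fold lower), Eng (1.56-fold lower) and Id3 (1.36-fold lower). Camera gave adjusted p = 0.0133 for this list, and adjusted p = 0.789 with an estimated correlation. The list call ended with fry, with scaling by library size only and with the C-rich trend removed, and Id3 lost its call with library size only.

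Growth and proliferation genes rose. Myc, a transcription factor that drives biosynthesis, went from 58.3 ± 2.86 to 157 ± 6.02 CPM, 2.68-fold higher. Odc1, the rate-limiting enzyme of polyamine synthesis, went from 482 ± 55.6 to 1426 ± 195 CPM. The nucleolar genes Ncl and Mybbp1a were 1.72-fold and 1.92-fold higher. On the Myc and ribosome biogenesis list 22 of 37 genes rose and none fell, and 24 rose adjusted over the list alone. On the replication list 22 of 39 rose and none fell, led by Pold1 (2.79-fold), Mcm2 (2.29-fold), Mcm4 (2.02-fold) and Uhrf1 (1.98-fold). Adjusted over that list alone, 24 rose and 1 fell. On the mitosis list 18 of 29 rose and none fell, with the same count over the list alone, among them Plk1 (2.25-fold), Kif20a (2.09-fold), Bub1 (2.08-fold) and Ccnb1 (1.71-fold). Median log2 fold changes of the 3 lists were 0.43, 0.67 and 0.59. Camera gave adjusted p = 3.45e-08, 3.27e-09 and 1.46e-07, and adjusted p = 0.315, 0.278 and 0.331 with an estimated correlation. On the list of cell cycle inhibitors, 1 of 17 genes passed the test over all genes and over the list alone. That gene, Ccng2, rose 1.92-fold, and camera gave adjusted p = 0.943.

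Metabolic genes rose too. Of 18 glycolysis genes 14 rose and none fell, and 15 rose adjusted over the list alone. The phosphofructokinase genes Pfkl and Pfkp were 2.35-fold and 2.18-fold higher, the lactate exporter gene Slc16a3 2.66-fold and the pyruvate kinase gene Pkm 1.77-fold. Of 11 hypoxia-responsive genes 9 rose, including Bnip3, Adm and P4ha1. Ddit4, an inhibitor of mTORC1 signalling, fell 6.38-fold. Adjusted over the list alone, 10 rose and 1 fell. On the list of amino acid, serine and one-carbon metabolism 10 of 20 rose and 2 fell (12 and 2 over the list alone), with Mthfd1, Shmt1 and Mthfd1l higher and the arginine transporter gene Slc7a1 2.67-fold lower. Camera gave adjusted p = 3.27e-08, 2.08e-05 and 0.00456 for these 3 lists, and adjusted p = 0.315, 0.315 and 0.431 with an estimated correlation. Nuclear genes of oxidative phosphorylation went both ways, 5 higher and 5 lower of 53 (5 and 2 over the list alone), and camera gave adjusted p = 0.653.

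Ribosomal protein genes fell, 41 of 77 against 2 that rose, and 45 against 2 over the list alone. Rps4x, Rpl23a and Rplp2 were between 2.15-fold and 2.24-fold lower. Camera gave adjusted p = 2.72e-06, and adjusted p = 0.860 with an estimated correlation. fry gave adjusted p = 0.0990. The endothelial identity list was mixed, with 4 of 19 higher and 6 lower, the same over the list alone, and camera gave adjusted p = 0.415. Cdh5, the gene of VE-cadherin, went from 1955 ± 37.5 to 401 ± 28.1 CPM and Erg fell 2.39-fold, while the angiopoietin receptor gene Tek rose 1.71-fold. Mitochondrially encoded transcripts were lower as a list (camera adjusted p = 0.0403, and adjusted p = 0.872 with an estimated correlation), a call lost with fry and without wt replicate 5, KO replicate 1 or KO replicate 2. Only mt-Nd6 passed among 13, over all genes and over the list alone, and it lost its call without KO replicate 1 or KO replicate 2.

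Over all genes, 3509 of 10952 were called between KO and wt by edgeR, 1610 higher and 1899 lower. At least 2-fold changes numbered 313 higher and 916 lower. The largest falls under the naming rule were Ppp1ccb, a transcribed pseudogene at 0 in both KO libraries and at least 126-fold lower, Lars2 (359.9-fold), the 7SL RNA genes Rn7s1 and Rn7s2 (139.7-fold each), which share reads, and the 7SK RNA gene Rn7sk (89.8-fold). The falls of Lars2 and of 7SL and 7SK RNA are part of the different makeup of the KO libraries. A batch of these libraries and the genotype cannot be told apart there. The largest rises were Pakap, at 0 in both wt libraries and at least 95.2-fold higher, A2m (10.2-fold), Tmem87a (9.80-fold), Chac1 (9.35-fold) and Rbm45 (8.88-fold). Tmem87a and Chac1 lie 1.05 and 0.0219 Mb from Dll4, so a variant haplotype carried with the floxed allele stays open for them. Pakap is annotated as overlapping other genes, so its reads are uncertain. Chac1 lost its call with limma-voom and without wt replicate 4 or KO replicate 2. The count was 2043 without wt replicate 4. Scaling by library size only moved the median log2 fold change of all genes from -0.02 to 0.35 and gave 3878 higher and 1034 lower, so directions here are relative to the bulk of genes. More genes rose than fell also with no filter (1911 and 1827) and with the C-rich trend removed (1871 and 1665). In every other setting more fell, so the balance of rises and falls depends on the processing.

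**Figure D2:**
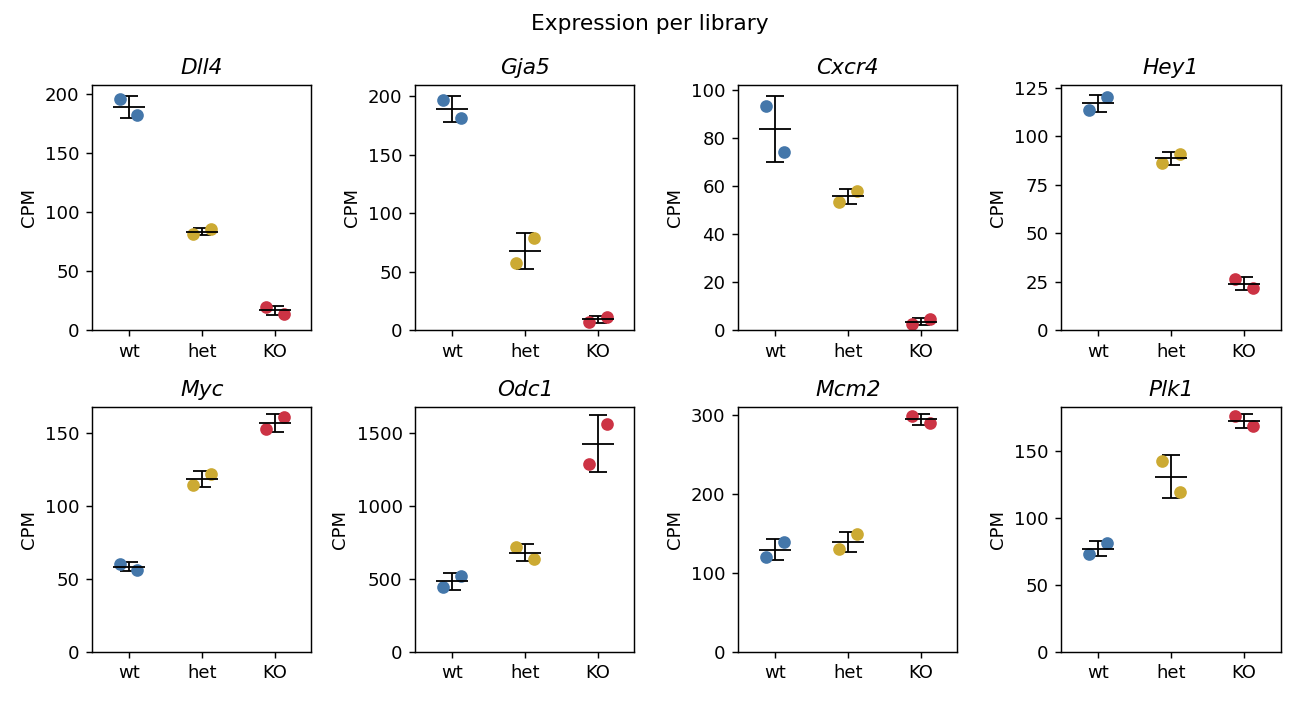
CPM (y axis) of 8 genes in wt, het and KO; points are single libraries, and the bar and whiskers give the mean and SD of 2 libraries. Dll4, Gja5, Cxcr4 and Hey1 were lower in both KO libraries than in both wt libraries, and Myc, Odc1, Mcm2 and Plk1 were higher.

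The comparison of het with wt asks what loss of 1 of the 2 alleles changes. Gja5 fell 2.73-fold, to 67.9 ± 15.5 CPM, and Myc rose 2.03-fold, to 118 ± 5.29 CPM. The immediate early gene Egr1 rose 1.94-fold and the mitotic kinase gene Plk1 1.69-fold. edgeR adjusted p was 7.35e-04, 0.00113, 0.00113 and 0.0193 in that order. Cxcr4 stood at 55.7 ± 3.19 CPM, Unc5b at 231 ± 0.0497, Slc45a4 at 57.3 ± 0.429 and Hey1 at 88.6 ± 3.47, and none of these passed the test. Hes1 stood at 157 ± 38.4 CPM against 97.6 ± 1.16 in wt, higher in both het libraries, and did not pass either. On the Notch target list none of 9 passed, 1 rose and 3 fell adjusted over the list alone, and camera gave adjusted p = 0.0993. Gja5 alone passed among the 25 arterial genes, and 8 were lower adjusted over the list alone. In 17 of the 25 both het libraries lay below both wt libraries. This held for 18.8% of all tested genes, and chance gives 16.7% for a single gene. The 25 genes share the same 4 libraries, so this count is a description and not a test. The arterial median was -0.39, with camera adjusted p = 8.59e-15, adjusted p = 0.0863 with an estimated correlation and adjusted p = 0.0299 with fry.

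The growth lists lay higher in het by camera, with medians of 0.16 for Myc and ribosome biogenesis, 0.20 for ribosomal proteins, 0.12 for replication and 0.17 for mitosis. Their adjusted p were 3.26e-05, 3.62e-13, 0.0180 and 8.16e-05, and adjusted p between 0.541 and 0.551 with an estimated correlation. The members that passed over all genes were Myc, Rps28 and Plk1, and none on the replication list. Adjusted over each list alone, 2, 12, 0 and 1 rose in that order. The replication call was lost without wt replicate 5 or het replicate 3, and the mitosis call without het replicate 3. The 4 lists did not pass with fry. Ribosomal proteins moved the other way in KO. Markers of other cells and of handling were higher in het as well. The cardiomyocyte list had a median of 1.28 with 10 of 14 members higher in both het libraries (19.2% of all tested genes were), camera adjusted p = 2.87e-10, and adjusted p = 0.0897 with an estimated correlation. Its members Tnnt2 and Actc1 stood at 30.3 ± 1.56 and 57.5 ± 7.30 CPM in het against 11.6 ± 0.631 and 33.4 ± 2.45 in wt, Tnni1 at 41.4 ± 15.0 against 37.5 ± 2.04 and Tpm1 at 237 ± 20.3 against 268 ± 17.8, and no member passed over all genes (6 rose over the list alone). Camera adjusted p was 5.24e-04 for mural cells and fibroblasts, 4.67e-05 for macrophages, 8.09e-09 for genes of the dissociation response and 0.00202 for mitochondrial transcripts, all higher in het, and adjusted p between 0.487 and 0.651 with an estimated correlation. The mural call was lost without wt replicate 4 or het replicate 3, the macrophage call without het replicate 2, and the mitochondrial call without wt replicate 4 or het replicate 3, where its direction turned in the second case. The calls of these 3 lists and of the dissociation list were also lost with fry (adjusted p = 0.511, 0.516, 0.529 and 0.320). Over all genes 1 of 16 dissociation genes passed (6 over the list alone) and none on the other 3 lists (2, 0 and 0 over the list alone). Capillary genes lay lower and feedback genes of ERK signalling higher (camera adjusted p = 0.00577 and 0.0170, and adjusted p = 0.541 and 0.487 with an estimated correlation). Of 10 capillary genes none passed, over all genes or over the list alone, and of 12 feedback genes 1, the Egr1 gene named above, rose in both. The first call was lost with fry and without het replicate 2, and the second without wt replicate 5 or het replicate 3. The list of sex-linked genes holds Xist and Y-linked genes, which move in opposite directions with the mix of sexes, so its direction describes only part of it. It lay lower (camera adjusted p = 0.0180, and adjusted p = 0.541 with an estimated correlation), a call lost with fry, with limma-voom, in a fit of wt and het alone, with thinning to equal totals or equal effective depth and without either wt or either KO library. Of its 5 genes none passed over all genes, and 1 rose and 3 fell over the list alone. Xist, expressed from the inactive X chromosome, stood at 254 ± 35.5 CPM in het, 86.3 ± 33.7 in wt and 26.2 ± 5.59 in KO, and the Y-linked gene Uty at 3.16 ± 1.45, 11.9 ± 4.33 and 18.1 ± 0.494 CPM. The Y-linked genes Kdm5d and Eif2s3y also lay lower in het than in wt (log2 fold change -1.29 and -1.56). In KO against wt Xist was called lower (log2 fold change -1.68, edgeR adjusted p = 0.00722) and Uty was not called. The mix of sexes may thus differ between the groups, and it cannot be told apart from the genotype.

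By edgeR 19 of 10952 genes were called between het and wt, 14 higher and 5 lower, and 893 had an unadjusted p under 0.05. In simulated counts 18 unchanged genes were called in this comparison beside 54 recovered changes of 1 on the log2 scale, so some of the 19 may be false. Calls of genes changed by 0.5 were not counted, so these numbers give no share of false calls. Under the naming rule the largest rises were Wdfy1 (4.41-fold), Rbm45 (3.70-fold), Dnajb14 (2.04-fold), Myc and Egr1, and the largest falls Gja5, Adamts8 (2.72-fold), Eif3j1 (2.30-fold), Dll4 and Sept4 (1.73-fold). Without wt replicate 4 the count was 2, with 1 of the 19 genes among them, and without het replicate 3 it was 76. It was 11 with limma-voom and 150 with no filter. Dll4, Gja5, Myc, Egr1 and Wdfy1 lost their calls without wt replicate 4 and in no other setting tried. Without wt replicate 4 or wt replicate 5, Rbm45, Dnajb14, Adamts8, Eif3j1, Sept4 and Plk1 lost theirs, and each of these 6 lost it without het replicate 2 or het replicate 3 as well. Rbm45 also lost its call with DESeq2, limma-voom, a fit of wt and het alone and thinning to equal totals, Adamts8 with limma-voom and both thinnings, Sept4 with thinning to equal effective depth, and Plk1 with limma-voom. Of the 19 genes, 12 were called in the same direction in KO against wt, 8 higher and 4 lower, and 3 (Dnajb14, Rps28 and Adamts8) in the opposite direction. Independent lists would share 2.06 higher and 0.867 lower. Simulated groups without any change, het and KO alike, shared at most 3 calls against common wt libraries. The simulated KO group lacked the changes of the real one, so few calls could be shared and this value sets no limit for the observed overlap. The covariance of the log2 fold changes over 7815 genes was 0.109 against a mean of 0.0314 and a highest value of 0.0386 simulated, while the correlation was 0.384 against 0.542 simulated. A split of the wt group would leave 1 library on each side and was not made, so part of the overlap beyond that of independent lists may come from the shared controls.

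The comparison of KO with het asks what loss of the remaining allele adds. Of 10952 genes 3412 were called, 1524 higher and 1888 lower. Arterial genes fell, 13 of 25 against 2 that rose, the same over the list alone, with a median of -0.60 (camera adjusted p = 3.78e-10, and adjusted p = 0.177 with an estimated correlation). Notch targets (4 of 9 lower, 1 higher), BMP and flow genes (7 of 13 lower, 1 higher) and ribosomal proteins (57 of 77 lower, 2 higher) fell. Replication (21 of 39), mitosis (15 of 29), glycolysis (12 of 18), hypoxia (10 of 11) and Myc and ribosome biogenesis genes (18 of 37) rose, against 2, 0, 0, 1 and 1 that fell. Camera adjusted p for these 8 lists lay between 1.54e-14 and 0.00458, and adjusted p between 0.278 and 0.664 with an estimated correlation. Adjusted over each list alone, 5, 7 and 63 fell, and 22, 17, 12, 10 and 18 rose, with 1, 1, 2, 2, 1, 0, 1 and 1 the other way. The BMP and flow call was lost without het replicate 2. The amino acid and one-carbon list was higher, with 9 of 20 up and 2 down, the same over the list alone (camera adjusted p = 0.0311, and adjusted p = 0.582 with an estimated correlation), a call lost with fry and without het replicate 2, het replicate 3 or KO replicate 2.

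Markers of cardiomyocytes were lower in KO than in het. Of 14, 12 fell and none rose, with 14 lower over the list alone (camera adjusted p = 4.01e-06, and adjusted p = 0.204 with an estimated correlation). Mural and fibroblast, macrophage and mitochondrial lists were lower too, with camera adjusted p = 0.0417, 0.0116 and 8.64e-04, and adjusted p = 0.753 for each with an estimated correlation. Of 11, 11 and 13 members 5, 4 and 4 fell and none rose (5, 7 and 4 lower over the list alone). The mural call was lost with fry and without het replicate 3 or KO replicate 2, the macrophage call with fry, with a mean CPM of at least 5, with thinning to equal totals and without het replicate 2 or KO replicate 2, and the mitochondrial call with fry. Tnni1 stood at 41.4 ± 15.0 CPM in het and 14.52 ± 0.334 in KO, Actc1 at 57.5 ± 7.30 and 16.3 ± 0.0557, Tpm1 at 237 ± 20.3 and 196 ± 15.3, and Tnnt2 at 30.3 ± 1.56 and 5.61 ± 0.221. Tpm1 did not pass over all genes, and with the C-rich trend removed it passed as higher in KO (log2 fold change 0.56, edgeR adjusted p = 3.05e-04, the lowest of a range up to 0.421 over the alternatives). The largest rises under the naming rule were Pakap (at least 104-fold), the Y-linked gene Uty (5.22-fold), the BMP ligand gene Bmp6 (4.93-fold), Adamts8 (4.24-fold) and the lactate transporter gene Slc16a1 (3.70-fold). Xist was lower in KO than in het (log2 fold change -3.26, edgeR adjusted p = 2.97e-04). The mix of embryo sexes may thus differ between these groups, and it cannot be told apart from the genotype. The largest falls were Ppp1ccb (at least 60.4-fold), Lars2 (368-fold), Rn7s1 and Rn7s2 (135-fold each) and the processed pseudogene Rps12l1 (109.8-fold), whose reads can be shared with Rps12. Those of Lars2, Rn7s1 and Rn7s2 carry the same limit as in KO against wt. Scaling by library size only gave 3930 higher and 1016 lower, and removal of the C-rich trend 1767 higher and 1695 lower.

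**Figure D3:**
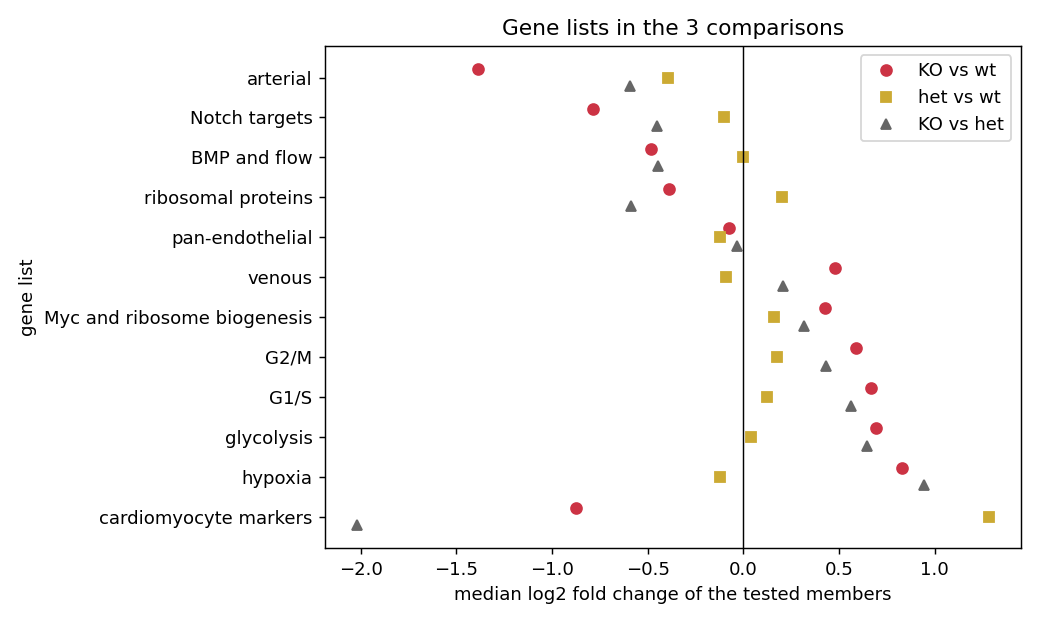
Median log2 fold change (x axis) of the tested members of 12 gene lists (y axis) in KO against wt (circles), het against wt (squares) and KO against het (triangles). The arterial medians were -1.39, -0.39 and -0.60, and the cardiomyocyte medians -0.88, 1.28 and -2.02; all medians are relative to TMM scaling.

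The design also allows the position of het between wt and KO to be measured. Het lay off the midpoint of the log scale in 1258 of 10952 genes, above it in 855 and below it in 403. Of the 3509 genes called between KO and wt, 1020 were off the midpoint, 1009 with het nearer wt and 11 with het nearer KO. A different preparation or sequencing of the KO libraries would also place het nearer wt and cannot be told apart from the genotype. These counts are therefore no measure of a response to Dll4 dose, and the same limit holds for the trend below. Scaling by library size only changed the count to 2162, with 559 above and 1603 below. The count was 775 without wt replicate 4, 758 without het replicate 2 and 779 with DESeq2. A linear trend on the number of lost alleles was called in 1515 genes, 770 rising and 745 falling. That count needed both libraries of wt and of KO. It fell when either wt library was left out, fell to a few genes without either KO library, and rose without either het library. It was 2909 with library size only (2396 rising and 513 falling), 2661 with no filter, 2528 with limma-voom and 879 with thinning to equal effective depth.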

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

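Of the settings below, thinning, list tests in a fit of 2 groups, removal of the C-rich trend, removal of abundant genes and restriction to protein-coding genes were chosen after the data were seen. With a library left out, the lone library of its group is assumed to vary like the others. No paired analysis was possible because wt shares no replicate number with the other groups, and het and KO share only 1. The KO comparisons could not be run without the KO libraries, which stand apart as a group.

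With an estimated correlation the lists called were 0 in KO against wt, 0 in het against wt and 0 in KO against het, against 11, 13 and 14 at the preset value, and with fry 3 in het against wt. Unfiltered, 150 genes were called between het and wt and 2661 in the dosage trend, where more genes of low count were tested. limma-voom called 11 and 2528. With library size only 2162 lay off the midpoint and 2909 followed the trend, as the scaling shifts KO against the rest. DESeq2 placed 779 off the midpoint. The cause was not tested for limma-voom and DESeq2. With each library left out, counts ranged from 2043 to 3815 in KO against wt, from 2 to 76 in het against wt, from 758 to 1153 off the midpoint and from 4 to 2202 in the trend. The lists called ranged from 10 to 13, from 11 to 14 and from 11 to 14 in the order above. The count in KO against het ranged from 2435 to 3206. Dll4 ranged from -3.78 to -3.29 in KO against wt, from -1.23 to -1.13 in het against wt and from -2.60 to -2.10 in KO against het. Fewer libraries left fewer degrees of freedom, which does not explain the counts that rose, and the cause of these was not tested. With library size only, the log2 fold changes of Tcf15 (-0.371 to 0.00905) and Egr1 (-0.373 to 0.00632) turned in KO against het. That scaling moved the median of all genes in this comparison from -0.02 to 0.36. With the C-rich trend removed, Tpm1 turned and passed as higher in KO against wt (0.42) and KO against het (0.56). Wt1 turned in KO against wt (0.11). No cause was tested for Tpm1 and Wt1. Without het replicate 3, mitochondrial transcripts turned lower in het against wt (camera adjusted p = 0.890; range without each library 3.72e-23 to 0.890) and endocardial markers lower in KO against het (0.0446; range 0.0446 to 0.959). Thinned to equal effective depth, the trend was called in 879 genes, with fewer counts. At the depth of these libraries, the shallowest with 1537908 counts, 54 of 100 simulated changes of 1 on the log2 scale were found in het against wt, so smaller ones may be missed.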

Other observations

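In KO against wt several gene groups not described above held called genes, while the groups did not pass camera at the preset correlation. On the tip cell list 10 of 20 genes rose and 4 fell (11 and 4 adjusted over the list alone; camera adjusted p = 0.154). The basement membrane gene Nid2 rose 2.17-fold and the peptide hormone gene Adm 2.78-fold, while the semaphorin receptor gene Plxnd1 fell 2.84-fold and Sparc 1.68-fold by edgeR with Benjamini-Hochberg adjustment. Among VEGF ligands and receptors 5 of 11 rose and 2 fell, the same over the list alone (camera adjusted p = 0.573). Vegfa rose 2.39-fold, Tek 1.71-fold and Flt4 1.51-fold, while Vegfc fell 6.53-fold, from 90.3 ± 2.97 to 13.9 ± 3.34 CPM (SD, n = 2). On the venous list Ephb4, Nrp2 and Il6st rose and Nr2f2, a transcription factor of venous identity, fell 2.63-fold (4 and 1 over the list alone, camera adjusted p = 0.396). Nrp2 lost its call without wt replicate 5 or KO replicate 2, and Il6st with DESeq2, with thinning to equal totals and without wt replicate 5 or KO replicate 1. Among interferon-responsive genes 5 of 11 fell and 1 rose, the same over the list alone (camera adjusted p = 0.396). Camera adjusted p lay between 0.177 and 0.943 for the lists of Notch machinery, capillary, endocardial and lymphatic genes, ERK feedback, cholesterol synthesis, dissociation, mural cells, red cells, macrophages, platelets and sex, and was 0.146 for cardiomyocyte markers, of which 5 of 14 fell (6 over the list alone). In KO against wt the median, the mean and camera's direction differed in sign for the lists of Notch machinery, VEGF ligands and receptors, oxidative phosphorylation, red cells and sex. They also differed for the venous, tip cell, BMP and flow, cell cycle inhibitor, oxidative phosphorylation and lymphatic lists in het against wt, and for Notch machinery, ERK feedback, cell cycle inhibitors, oxidative phosphorylation, endocardium and red cells in KO against het. No list called by camera in these 3 comparisons was among them. Lists not called had camera adjusted p between 0.0553 and 0.997 in het against wt and between 0.122 and 0.951 in KO against het. The epicardial list had 2 tested members and was not tested.

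Some genes were at 0 in every library of 1 group. At 0 in both wt libraries and at 5 CPM or more in the other 4 were 4 genes, each a pseudogene (Gm6768, Tdg-ps, Gm8730 and Gm9855), against 1 at 0 in het only (ENSMUSG00000044341) and 5 at 0 in KO only (Gm10288, Gm20431, Gm20425, Ppp1ccb and Eif4a-ps4), of which 3 were pseudogenes. They were chosen after their values were seen. Pseudogene reads are shared with their parent genes.

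All tests in the rest of this part, with their windows and thresholds, were chosen after the results were seen. The first pattern is the large number of genes called between KO and the other groups. With all libraries thinned to equal effective depth (library size times TMM factor) 2832 genes were called between KO and wt, without Lars2, mitochondrial ribosomal RNA, Gm42418 and the 7S genes 3566, and with the C-rich trend removed 3536, against 3509. Of the 3509, 2685, 3416 and 3211 kept their call and direction in that order. Depth and the mean C-rich trend therefore do not account for the count as a whole. Removing the abundant genes says little, because TMM scaling already allows for a few such genes. The trend itself was there, since the median log2 fold change was 0.09 among 2337 genes with 13 cytosines in their most C-rich 20 nt window and -0.70 among 265 genes with 17, while in het against wt these medians were 0.01 and 0.02. It was found by looking through GC content, length and the richest window of each base, for which Spearman correlations across genes, which are not independent, were -0.0210, 0.0341, -0.163 for C, -0.0800 for A, -0.0657 for G and -0.0204 for T in KO against wt, and GC content reached 0.140 in het against wt. A different preparation or sequencing of the KO libraries may underlie part of it and cannot be told apart from the genotype, because the lowest Lars2 share in wt and het was 267 times the highest in KO and no batch is recorded.

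The second pattern is the lower arterial list. In a fit of wt and het alone, which holds no KO library, its median was -0.39 (camera adjusted p = 1.48e-15, adjusted p = 0.337 with an estimated correlation and adjusted p = 0.0784 with fry). This fit repeats the het against wt contrast on the same libraries, so it is not independent support. In the fit of all 6 libraries that contrast also had a median of -0.39, with fry adjusted p = 0.0299. The fall may not rest on the KO libraries alone, but the tests with an estimated correlation and with fry in the fit of wt and het leave this open.

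The third pattern concerns neighbours of Dll4, since within 5 Mb of it 6 of 77 other tested genes had an edgeR p under 0.01 in het against wt, against 277 of 10874 elsewhere (Fisher's exact odds ratio 3.23, two-sided p = 0.0145; 2.32 and p = 0.151 within 2 Mb, 2.70 and p = 0.00911 within 10 Mb). Eif3j1 stood at 82.7 ± 5.60, 36.3 ± 4.01 and 7.47 ± 1.19 CPM in wt, het and KO, and Tmem87a at 4.67 ± 0.553, 15.7 ± 2.02 and 45.6 ± 9.91 CPM, and Hypk also lay further from wt in KO than in het. Chac1 did not separate KO (5.45 and 14.8 CPM) from het (8.55 and 8.38 CPM). Ppip5k1 lay higher in het (log2 fold change 0.85) but not in KO (-0.15, edgeR adjusted p = 0.699), and Dnajc17 was no lower in KO (-1.47) than in het (-1.70). A share as high was found in 2.37% of 8541 other windows of 5 Mb on each side, which overlap and are not independent, and a variant haplotype carried with the floxed allele may underlie it. In KO against wt, where the same haplotype would be present, the odds ratio was 1.40 (two-sided exact p = 0.167). There 29.0% of genes elsewhere already had p under 0.01, against 36.4% in the window. With so many genes changed everywhere, this comparison could hardly show a local excess and decides nothing. A haplotype therefore stays open, as does a response of neighbours to Dll4 loss, which was not tested.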
